A study of Mus musculus with 6 samples.

How the data were processed

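Total RNA from the gastrocnemius muscle of 26-month-old mice was made into 3′ mRNA sequencing libraries from 500 ng of RNA with a Lexogen QuantSeq kit, per the labels' protocols. QuantSeq is designed to prime on the poly(A) tail and read 1 tag near the 3′ end of each transcript. A count is then not multiplied by transcript length, and isoforms with a shared 3′ end are counted together. Whether these libraries kept to that design was not tested. The very long titin transcript, Ttn, took 5.77% to 8.70% of a library, so a dependence of counts on length cannot be excluded. The deposited tables held raw read counts per gene symbol, 1 table per library, with no header beyond the column name; whole numbers with totals that differ between libraries identified the unit. Bowtie2 and bedtools with the mm10 mouse build are named in the submitters' processing notes. The versions of both tools, the gene annotation, the treatment of reads with several matches, the handling of strand and of copied reads, and any trimming are not given in the sources used here. Bowtie2 does not split a read over an intron, so reads that cross a splice junction near the 3′ end can be lost.

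Each table listed 23282 features under 23238 distinct symbols. 35 symbols stood on more than 1 line, and their counts were summed. No mitochondrially encoded transcript was listed, so the planned share of mitochondrially encoded counts and the planned fit without these transcripts could not be computed. The 45S ribosomal RNA precursor Rn45s was listed and took 4.97% to 15.4% of a library. The antisense gene Tsix held 95.9% to 99.0% as many counts as Xist in each library, so overlapping genes on opposite strands were not separated. Among features with a mean of at least 20 counts, 16 had counts identical to another feature in all 6 libraries. The haemoglobin symbols Hbb-bs and Hbb-b1, which the fixed lists treat as the same gene, had almost the same counts. Values of overlapping, antisense or duplicated genes are therefore uncertain.

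Libraries were grouped by the sample titles into vehicle (n = 3) and farnesol (n = 3). The labels call the libraries biological replicates and do not say whether each came from a separate mouse, so p-values measure the spread between these libraries. Total counts ran from 9895700 to 12707751 per library. A count of 0 allows up to 3 counts, which is 0.236 to 0.303 CPM (counts scaled to a common library size) depending on the library. This limit covers counting error only, because whether copied reads were removed is not given.

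The test for single genes was edgeR 4.0.16 in R 4.3.3: filterByExpr by group, trimmed-mean (TMM) scaling factors, estimateDisp and glmQLFit with robust = TRUE, and glmQLFTest on the group term, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 11674 genes. TMM factors ran from 0.905 to 1.14 and the common biological coefficient of variation was 25.7%. Standard errors were taken as the absolute log2 fold change over the square root of F, and 95% intervals used the t distribution on the fit's degrees of freedom. CPM values used TMM-scaled library sizes, and means are given with the SD of 3 libraries.

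A total of 43 gene lists (pathways of muscle, mitochondrial, lipid and stress biology, and markers of the other cell types that a muscle sample can hold) and 16 core genes were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The rule took the 16 core genes, then up to 12 genes per direction past the threshold with separated groups. These also needed a mean of at least 2 CPM and a symbol that is not a gene model name. With fewer than 6, genes of smallest unadjusted p filled each direction to 6, under the same conditions on mean and symbol but not on separation. From each described list it took up to 4 members of smallest unadjusted p and any past the threshold. Some genes that this rule names are not reported here. Genes named outside this rule were chosen after their values were seen. Lists with at least 5 tested members, 38 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The same lists were tested with camera and an estimated correlation, and with fry, which tests whether the genes of a set move on balance in 1 direction and does not compare the set with other genes. Reactome sets of 10 to 300 tested genes came from the fgsea 1.28.0 package; 6998 of its 7111 gene identifiers matched a symbol in the RefSeq table of GRCm38.p6. Shares and group differences of single values were compared by exact two-sided permutation tests, for which 3 against 3 libraries allow no p below 0.1.

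Gene positions are from the RefSeq table of GRCm38.p6, whose chromosomes are those of mm10, and are 1-based. Transcript lengths are those of the longest transcript of a symbol in the GENCODE vM21 annotation of the same build and were found for 99.3% of tested genes.

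The gene test was tested on simulated data drawn from the observed means, library sizes and dispersions, with 200 genes changed in each of 5 simulations and a median of 11389 genes tested. It recovered 8.06% of 1.5-fold changes, 42.4% of 2-fold changes and 82.1% of 4-fold changes. For genes of at least 50 CPM the shares were 25.8%, 94.8% and 98.5%. Over the 5 simulations, 39 unchanged genes were called. With a log2 shift of 0.2 given to the subunits of oxidative phosphorylation and genes otherwise independent, camera with the preset correlation called 15 of 15 shifted lists and 1 of 170 unshifted lists.

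Alternatives were other scaling factors (DESeq2 median of ratios, upper quartile, library totals), no filter, a filter of at least 5 CPM in at least 3 libraries, no robust fit, a log2 fold threshold of 1, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn. After the data were seen, a fit without Rn45s and a fit on counts divided by the estimated number of reads per molecule were added. Also chosen then were the adjustment over single lists with each library left out, the correlation of each library with transcript length, and every alternative for the Reactome sets. Figures were drawn with matplotlib 3.10.9.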

Results

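Gene expression was measured in the gastrocnemius, a calf muscle built mainly of fast fibres, of aged wild-type C57/BL6J mice. The mice were 26 months old and received by mouth, for 30 days, either farnesol at 350 mg/kg or its vehicle, saline with 5% DMSO. Farnesol is a sesquiterpene alcohol, the free alcohol of the farnesyl group that farnesyltransferase attaches to proteins. The 3 vehicle libraries held 11058539, 10931849 and 10354759 counts and the 3 farnesol libraries 10231046, 12707751 and 9895700 counts. Between 13851 and 14331 genes had at least 1 count, and the farnesol mean exceeded the vehicle mean by 88.7 genes (exact permutation p = 0.6, n = 3 and 3; the smallest p this design allows is 0.1). Profiles of log2 CPM correlated across genes at 0.947 to 0.956 within groups and at 0.945 to 0.959 between groups.

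Farnesol was compared with vehicle to ask how the transcripts of aged muscle differ after feeding, in a study whose title names the farnesylation of PARIS, the repressor of the mitochondrial regulator PGC-1α. Adipocyte markers were higher after farnesol as a list (18 of 19 members, median log2 fold change 0.34), a call of camera at its preset correlation that was lost with an estimated one (adjusted p = 0.167 with an estimated correlation). Of its members, which did not pass over all genes, Scd1, the stearoyl-CoA desaturase, was 1.88-fold as abundant (95% interval 1.45 to 2.44, n = 3 and 3) and Fasn, the fatty acid synthase, 2.61-fold (1.54 to 4.43). The 3 lists of nuclear respiratory chain and ATP synthase subunits had medians of 0.17 to 0.23, and of 0.09 to 0.14 without farnesol replicate 1. Their calls too were lost with an estimated correlation (adjusted p = 0.445 to 0.547 with an estimated correlation). Fbxo32, the muscle ubiquitin ligase atrogin-1, stood at 0.654-fold (0.517 to 0.827) and did not pass over all genes. The transcripts of PARIS itself and of PGC-1α did not differ detectably.

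Over all 11674 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 351 genes (3.01%, with 5% given by chance) had an unadjusted p under 0.05. DESeq2, on 16624 genes without this filter, and limma-voom, on the 11674, also called 0 genes, with smallest adjusted p of 0.0887 and 0.565. Without the filter edgeR called 13 genes. In 1030 genes (8.82%) the 3 farnesol values did not overlap the 3 vehicle values, where chance gives 10%. Every fold change of a single gene from all 6 libraries is a value of the filtered fit that did not pass over all genes, and those called when adjusted over the list alone are named as such.

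Zfp746 (PARIS; chromosome 6, 48062391 to 48086986, mm10) was measured at 4.60 ± 2.23 CPM (SD, n = 3) in vehicle and 4.63 ± 1.62 CPM in farnesol libraries. Its log2 fold change was 0.00 (SE 0.45) with a 95% interval for the fold of 0.527 to 1.90, from a mean of 50.5 counts per library. Ppargc1a (PGC-1α; chromosome 5, 51454249 to 52115853) stood at 93.2 ± 24.1 and 96.4 ± 19.9 CPM, a log2 fold change of 0.05 (SE 0.20) and a fold of 1.03 (0.780 to 1.37). The axis of 24 genes around PARIS and PGC-1α split into 14 higher and 10 lower members, with a median log2 fold change of 0.03 (camera adjusted p = 0.792; −0.01 to 0.08 with 1 library left out). Of its members, Esrrg, an oestrogen-related receptor of oxidative metabolism, had a log2 fold change of 0.39 (SE 0.26), Nrf1 of 0.25 (SE 0.34) and the mitochondrial transcription factor Tfam of −0.28 (SE 0.21).

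Genes of protein prenylation did not pass as a set (16 tested, 9 higher and 7 lower, median 0.02, camera adjusted p = 0.733). Their median ran from −0.01 without vehicle replicate 1 to 0.15 without farnesol replicate 3. Fnta, the shared alpha subunit of farnesyltransferase and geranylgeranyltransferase I, was at 68.1 ± 2.17 and 76.3 ± 5.06 CPM (log2 fold change 0.16, SE 0.16), and Fntb, the farnesyltransferase beta subunit, at 14.6 ± 2.41 and 13.1 ± 3.90 CPM (−0.15, SE 0.26). Sterol and mevalonate synthesis genes numbered 13 higher and 10 lower of 23, with a median of 0.13 (camera adjusted p = 0.439), which was 0.01 without vehicle replicate 2. Hmgcs1, a synthase of the mevalonate pathway, had a log2 fold change of 0.03 (SE 0.22). Of the remaining genes fixed in advance, Pdk4 (−0.15, SE 0.58), Mstn (−0.24, SE 0.23), Cdkn1a (0.10, SE 0.16), Myh7 (0.33, SE 0.30) and Myh4 (−0.16, SE 0.21) had intervals that included 0.

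**Figure D1:**
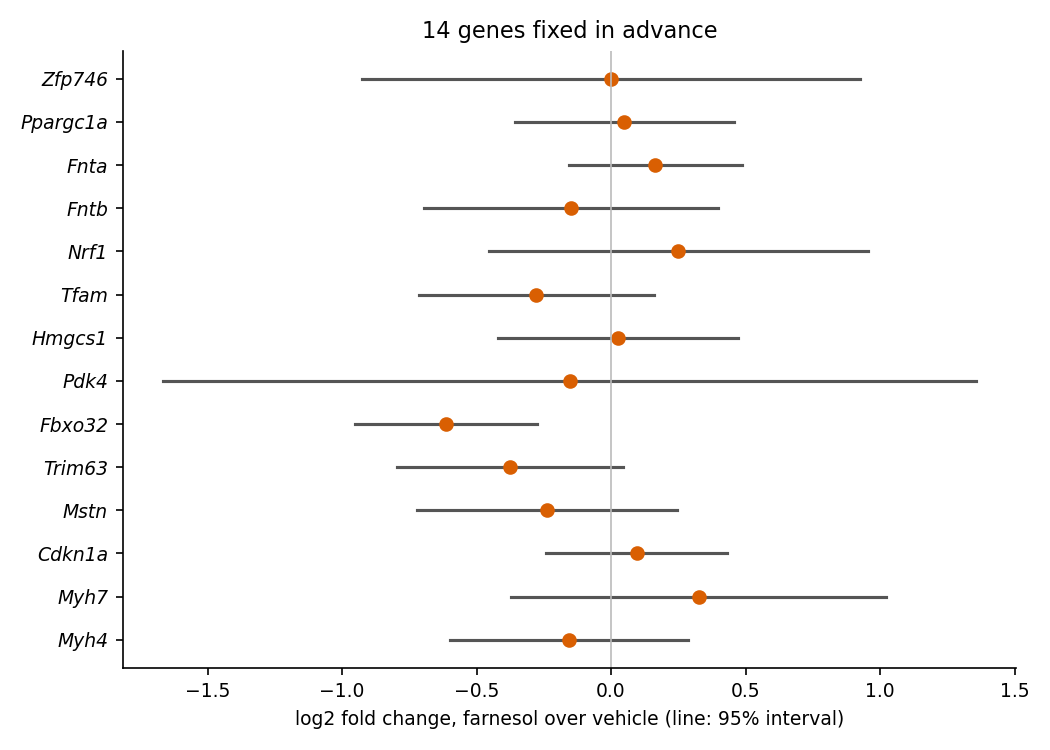
Log2 fold change of farnesol over vehicle (x axis) for 14 genes fixed in advance (y axis), with points for the edgeR estimate and lines for its 95% interval, n = 3 and 3 libraries. The interval of Fbxo32, −0.95 to −0.27, lies below 0, and those of the other 13 genes include 0.

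Of the 38 lists tested, 13 passed an adjusted p of 0.05 with camera at the preset correlation, 11 of them higher and 2 lower after farnesol. None kept its call with an estimated correlation, where the smallest adjusted p was 0.167, or with fry, where the smallest was 0.507. The estimated correlation was 0.013 for muscle atrophy genes and −0.078 for neutrophil and mast cell markers, against the preset 0.01. In the other called lists it ran from 0.043 (adipocyte markers) to 0.516 (erythroid markers). A higher correlation thus does not account for every lost call. With an estimated correlation camera also uses the few residual degrees of freedom of the libraries, where at a preset one it uses the number of genes. That gives larger p-values to like shifts. The shares of the 2 differences in the lost calls were not separated. In 6 lists the library means of the groups did not overlap, against 3.8 given by chance.

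Adipocyte markers rose as a list: 18 of 19 tested members were higher, with a median log2 fold change of 0.34 (camera adjusted p = 4.3e-11; adjusted p = 0.167 with an estimated correlation). Over all genes 0 members passed, and 3 passed when adjusted over the list alone in edgeR. These were Scd1 (chromosome 19, 44394450 to 44407709; 52.9 ± 8.38 to 99.4 ± 22.4 CPM, adjusted p = 0.000916), Fasn (chromosome 11, 120805958 to 120825166; 12.1 ± 7.35 to 31.5 ± 4.29 CPM, adjusted p = 0.0171) and Cidec, a protein of the lipid droplet surface (chromosome 6, 113424634 to 113435760; 16.3 ± 6.43 to 30.0 ± 4.14 CPM, adjusted p = 0.0183). The leptin gene Lep stood at 3.84 ± 1.17 and 7.82 ± 2.04 CPM, with an adjusted p of 0.0526 over the list alone in edgeR. With each library left out in turn, Scd1 passed over the list alone in 6 of 6 fits. Fasn was lost without farnesol replicate 2 (adjusted p = 0.0504) and Cidec without farnesol replicate 1 (0.12) or vehicle replicate 2 (0.0790). The list's median was 0.22 without vehicle replicate 2 and 0.67 without vehicle replicate 3.

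**Figure D2:**
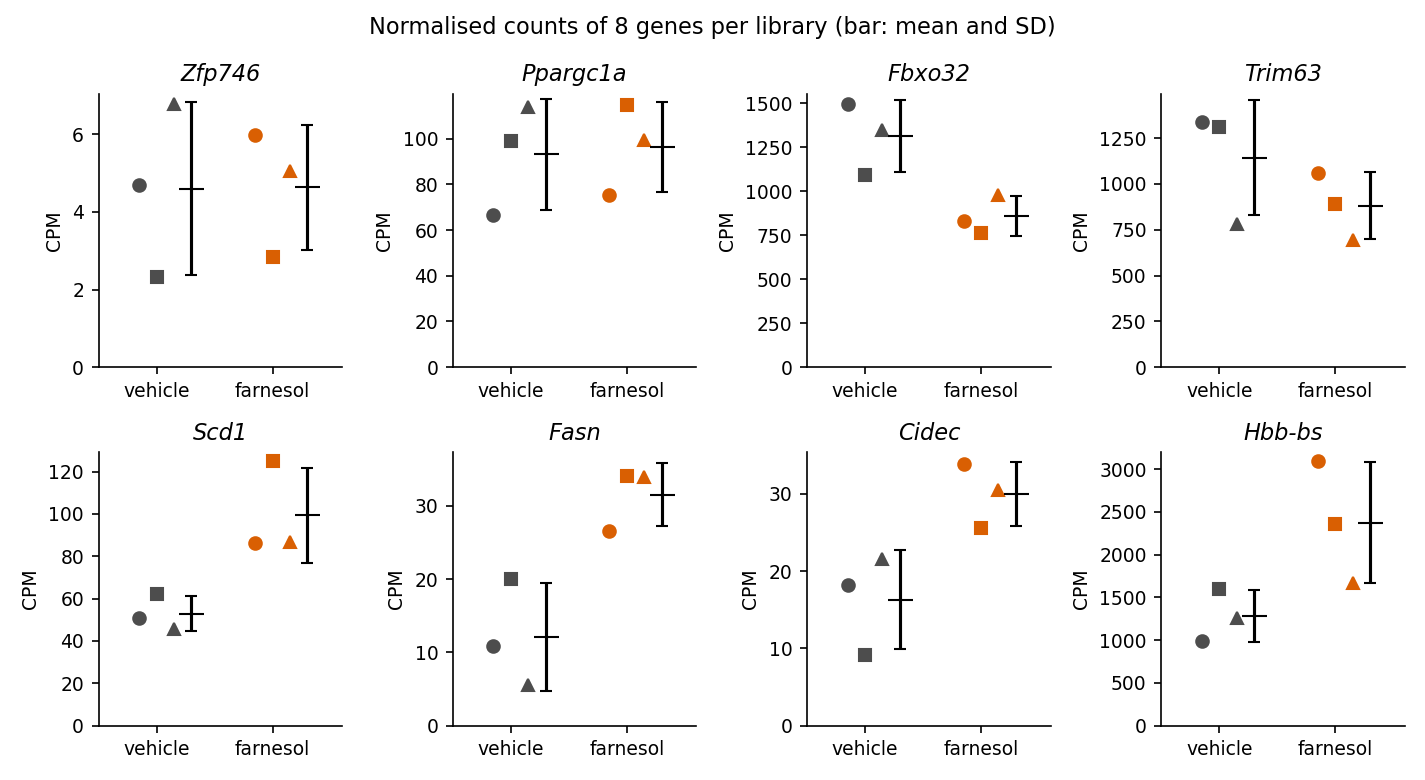
TMM-normalised CPM (y axes, starting at 0) of 8 genes in vehicle (grey) and farnesol (orange) libraries, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for mean and SD (n = 3). Scd1, Fasn, Cidec and Hbb-bs were above and Fbxo32 below the vehicle range in every farnesol library, while Zfp746, Ppargc1a and Trim63 overlapped.

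The nuclear-encoded subunits of oxidative phosphorylation rose as lists at the preset correlation. Complex I had 34 of 36 members higher with a median log2 fold change of 0.17 (camera adjusted p = 1.6e-07; adjusted p = 0.547 with an estimated correlation). Complexes II to IV had 25 of 27 higher with a median of 0.22 (7.1e-09; adjusted p = 0.547 with an estimated correlation), and ATP synthase 17 of 18 with a median of 0.23 (4.0e-07; adjusted p = 0.445 with an estimated correlation). No member passed in edgeR, over all genes or adjusted over the list alone. Cox8b, a muscle isoform of cytochrome c oxidase, stood at 172 ± 28.9 and 258 ± 69.0 CPM (log2 fold change 0.59, SE 0.18), Uqcr10 of complex III at 149 ± 17.7 and 215 ± 61.2 CPM (0.53, SE 0.18), Cox7a1 at 149 ± 0.532 and 208 ± 64.5 CPM (0.48, SE 0.18), and Ndufb2 of complex I at 85.6 ± 6.37 and 111 ± 9.98 CPM (0.37, SE 0.15). The genes of mitochondrial ribosomes and import (29 of 33 higher, median 0.19) passed too, with a camera adjusted p of 8.6e-06 (adjusted p = 0.445 with an estimated correlation).

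One farnesol library stood apart in these groups. The mean log2 CPM of the 81 subunits in farnesol replicate 1 lay 0.28 above the mean of the 6 libraries, while the other 5 libraries lay between −0.15 and 0.02. Farnesol replicate 1 was also the highest library for adipocyte markers, at 0.44 against 0.16 and 0.21 in farnesol replicates 2 and 3. The same held for fatty acid uptake and oxidation, the tricarboxylic acid cycle, cytosolic ribosomal proteins, and neutrophil and mast cell markers. In the same library Rn45s took 4.97% of counts against 9.92% to 15.4% elsewhere. Deviations of log2 CPM from the gene's mean correlated across genes with transcript length at −0.24 (Spearman) in farnesol replicate 1 and at 0.02 to 0.10 in the other 5 libraries. Genes are not independent replicates. Without farnesol replicate 1 the medians were 0.09 for complex I, 0.10 for complexes II to IV, 0.14 for ATP synthase and 0.11 for mitochondrial ribosome and import genes, and the 4 lists stayed past the threshold at the preset correlation. The log2 fold changes of Cox8b, Uqcr10 and Cox7a1 were then 0.37, 0.27 and 0.19.

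Fatty acid uptake and oxidation rose as a list (28 of 30 higher, median 0.17, camera adjusted p = 0.000102; adjusted p = 0.445 with an estimated correlation). Fabp3, the muscle fatty acid binding protein, was at 271 ± 69.2 and 391 ± 95.3 CPM (log2 fold change 0.53, SE 0.20), and Acaa2, a thiolase of beta-oxidation, at 108 ± 10.1 and 134 ± 9.08 CPM (0.30, SE 0.15). Without vehicle replicate 1 the median of this list was 0.11. The tricarboxylic acid cycle had 20 of 23 members higher with a median of 0.15 (camera adjusted p = 0.000414; adjusted p = 0.547 with an estimated correlation), and its call was lost without vehicle replicate 1, at a median of 0.10. Citrate synthase, Cs, stood at 213 ± 41.6 and 257 ± 11.3 CPM (0.27, SE 0.16).

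Slow fibre genes rose as a list, with 18 of 21 higher and a median of 0.21 (camera adjusted p = 0.000239; adjusted p = 0.547 with an estimated correlation). Sln, the sarcolipin that regulates the calcium pump, was at 15.2 ± 6.79 and 29.8 ± 9.24 CPM (log2 fold change 0.97, SE 0.33) and the slow myosin light chain Myl2 at 157 ± 23.7 and 211 ± 45.4 CPM (0.43, SE 0.17). This call rested on farnesol replicate 2, without which the median was 0.08 and the list no longer passed; without farnesol replicate 1 it was 0.33. Fast fibre genes (15 of 21 higher, median 0.07, camera adjusted p = 0.332; −0.07 to 0.15 with 1 library left out) and glycolysis and glycogen genes (15 of 29 higher, median 0.02, 0.677; −0.01 to 0.11) did not pass. PPAR target genes, among them Cidec, did not pass either (13 of 21 higher, median 0.11, camera adjusted p = 0.124).

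Muscle atrophy genes fell as a list, with 22 of 29 lower and a median log2 fold change of −0.14 (camera adjusted p = 0.00231; adjusted p = 0.445 with an estimated correlation). Fbxo32 (chromosome 15, 58175879 to 58214892) went from 1312 ± 205 to 858 ± 112 CPM, a log2 fold change of −0.61 (SE 0.16), and was the 1 member that passed when adjusted over the list alone in edgeR (adjusted p = 0.0311). It also passed over the 16 core genes alone (edgeR adjusted p = 0.0172), and there in 3 of the 6 fits with a library left out, lost without vehicle replicate 1 (0.197), farnesol replicate 1 (0.0530) or farnesol replicate 2 (0.166). Its log2 fold change lay between −0.73 and −0.51 with each library left out, and it passed over the atrophy list alone in 2 of these 6 fits, without vehicle replicate 2 (0.0109) and without farnesol replicate 3 (0.0374). The highest was 0.145, without vehicle replicate 1. Trim63, the ligase MuRF1, stood at 1142 ± 312 and 880 ± 183 CPM (−0.38, SE 0.20), the glucocorticoid-induced Fkbp5 at 56.4 ± 6.13 and 36.1 ± 11.8 CPM (−0.64, SE 0.21) and Sesn1 at 28.2 ± 4.33 and 21.3 ± 2.65 CPM (−0.41, SE 0.21). The list's call was lost without vehicle replicate 1 (median −0.12) and without farnesol replicate 3 (median −0.08). Proteasome subunits (23 of 31 lower, median −0.09, camera adjusted p = 0.0638) did not pass in the full set and passed without vehicle replicate 2 (−0.15) or farnesol replicate 1 (−0.12), while the median was −0.04 without vehicle replicate 1.

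Among blood and immune markers, erythroid genes rose as a list (7 of 10 higher, median 0.37, camera adjusted p = 0.000239; adjusted p = 0.547 with an estimated correlation). The groups overlapped: the list mean was −0.43 in farnesol replicate 3, below 0.12 and 0.15 in vehicle replicates 2 and 3. The members that moved were globins: Hbb-bs (chromosome 7, 103826523 to 103827928) went from 1286 ± 304 to 2375 ± 712 CPM, Hba-a1 from 2774 ± 695 to 4706 ± 1283 CPM and Hbb-bt from 379 ± 72.0 to 544 ± 136 CPM. These 3 passed when adjusted over the list alone in edgeR, with adjusted p of 0.00603, 0.00992 and 0.0342, and globin copies can share reads. Without vehicle replicate 1 or farnesol replicate 1 the 3 genes no longer passed over the list alone, and the list lost its call without vehicle replicate 1 (median 0.21). Without vehicle replicate 3 or farnesol replicate 2, Hbb-bt alone no longer passed. The red cell membrane marker Slc4a1 (−0.68, SE 0.72), chosen after its values were seen, was at most at 2.30 CPM in either group mean.

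Macrophage markers fell as a list, with 19 of 21 lower and a median of −0.31 (camera adjusted p = 0.00632; adjusted p = 0.547 with an estimated correlation). Adgre1, the F4/80 antigen, was at 5.94 ± 0.637 and 2.87 ± 1.28 CPM (log2 fold change −1.04, SE 0.42) and Lyve1, of resident macrophages and lymphatic vessels, at 53.3 ± 8.49 and 39.6 ± 3.11 CPM (−0.43, SE 0.18). Vehicle replicate 3 held the highest macrophage mean, 0.69 above the mean of the 6 libraries. Without it the median was −0.10 and the call was lost, as it was without farnesol replicate 3 (−0.28) and with the filter of 5 CPM (−0.19); without vehicle replicate 2 the median was −0.49. Interferon and antigen presentation genes did not pass (14 of 26 lower, median −0.13, camera adjusted p = 0.0966), although each farnesol library mean lay below each vehicle mean (exact permutation p = 0.1). Its member Irf9, a subunit of the interferon-activated factor ISGF3, stood at 8.71 ± 0.736 and 4.30 ± 0.755 CPM (−1.02, SE 0.33). Inflammation and NF-κB targets (14 of 18 lower, median −0.23, camera adjusted p = 0.0711) did not pass in the full set. Their mean was −0.56 in farnesol replicate 3, against 0.20 and −0.07 in farnesol replicates 1 and 2. The 1 member with an unadjusted edgeR p under 0.05, Nfkb2, rose (log2 fold change 0.67, SE 0.21). Both lists passed without farnesol replicate 1 (medians −0.18 and −0.33), the interferon list also without vehicle replicate 1 (−0.26) and the inflammation list without vehicle replicate 2 (−0.28). Without vehicle replicate 3 the medians were −0.01 and −0.14, and the interferon median was 0.07 with the filter of 5 CPM.

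**Figure D3:**
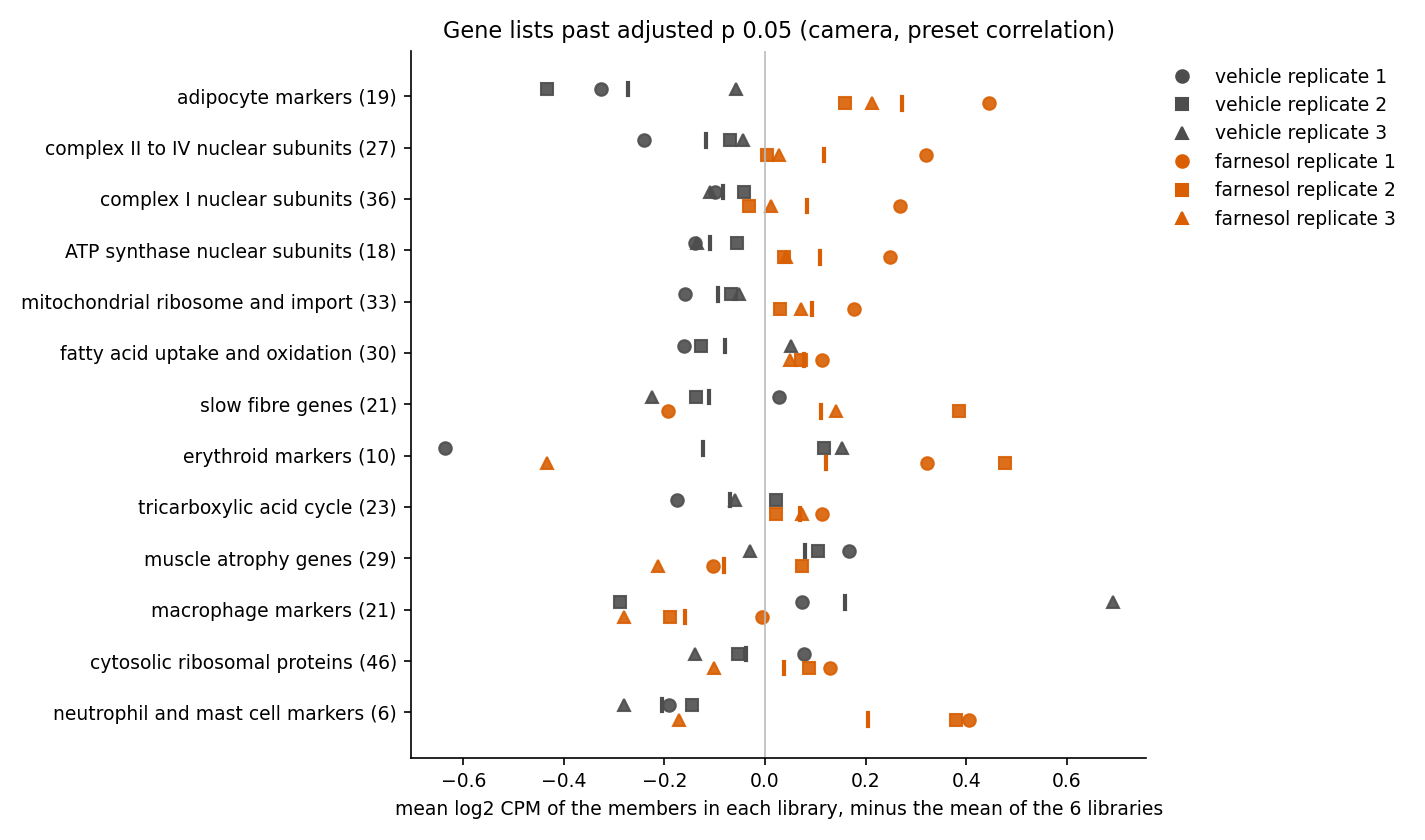
Mean log2 CPM of the members of each of the 13 lists in each library, minus the mean of the 6 libraries (x axis), for vehicle (grey) and farnesol (orange) libraries, with bars for group means and the number of tested members in brackets. Farnesol replicate 1 (orange circle) was the highest library for the subunits of complexes I to IV and ATP synthase, and vehicle replicate 3 (grey triangle) for macrophage markers.

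Cytosolic ribosomal proteins (38 of 46 higher, median 0.07, camera adjusted p = 0.0177; adjusted p = 0.881 with an estimated correlation) and neutrophil and mast cell markers (6 of 6 higher, median 0.33, 0.0476; adjusted p = 0.445 with an estimated correlation) passed narrowly. The ribosomal call was lost without vehicle replicate 2 (0.08), vehicle replicate 3 (0.03), farnesol replicate 1 (0.04) or farnesol replicate 2 (0.06), and without vehicle replicate 1 the median was 0.15. The neutrophil and mast cell call was lost in 5 of the 6 leave-one-out fits, with medians of 0.30 to 0.44, and held without farnesol replicate 3 alone (0.48). Mcpt4, a mast cell protease, stood at 1.85 ± 0.285 and 4.34 ± 0.960 CPM (log2 fold change 1.22, SE 0.47).

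Lists of endothelial (median −0.00, camera adjusted p = 0.972), smooth muscle and pericyte (−0.01, 0.792), tendon (−0.00, 0.758), Schwann cell (0.10, 0.237), fibroblast and fibro-adipogenic progenitor (0.10, 0.237) and satellite cell and myogenic genes (−0.05, 0.729) did not pass. Nor did those of autophagy and mitophagy (0.01, 0.912), antioxidant genes (0.01, 0.912), heat shock (−0.00, 0.895), unfolded protein and amino acid response (−0.08, 0.364), senescence and p53 targets (−0.03, 0.912), immediate early genes (−0.04, 0.917), the circadian clock (−0.11, 0.303), extracellular matrix and fibrosis (0.03, 0.677), denervation and neuromuscular junction (0.10, 0.420) and calcium handling (0.02, 0.357). With 1 library left out, the medians of these lists lay between −0.20 (clock, without farnesol replicate 1) and 0.32 (Schwann cell, without vehicle replicate 2). All of them but the Schwann cell and clock lists changed sign in at least 1 such fit. The clock median was −0.00 without farnesol replicate 3. The test's direction differed from the sign of the median for satellite cell, tendon, heat shock, autophagy, antioxidant and senescence lists, and from that of the mean for satellite cell, prenylation, senescence and smooth muscle lists.

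Genes were ranked by p among those with a mean of at least 2 CPM and a symbol that is not a gene model name. The first 6 among those higher were Scd1, Tppp3, Hbb-bs, Hbb-b1, Urm1 and Fasn, with edgeR adjusted p from 0.563 upwards. Tppp3, a tubulin-binding protein found in tendon sheath and connective tissue cells, was at 17.2 ± 4.12 and 32.8 ± 5.14 CPM (1.90-fold, 1.38 to 2.62), and Urm1, a ubiquitin-like sulphur carrier for transfer RNA modification, at 6.26 ± 0.535 and 14.7 ± 6.68 CPM (2.34-fold, 1.48 to 3.70). Hbb-b1 had a log2 fold change of 0.89 (SE 0.21) and nearly the counts of Hbb-bs. It is thus not a separate finding, here or among the genes called without the filter. Among those lower were Fbxo32, Zfp653, Iigp1, Cyp26b1 and Mfap1b. Zfp653, a zinc finger repressor, stood at 4.33 ± 0.0800 and 1.17 ± 0.361 CPM (0.271-fold, 0.128 to 0.573), and Iigp1, an interferon-inducible GTPase, at 14.3 ± 5.26 and 6.13 ± 2.94 CPM (0.426-fold, 0.260 to 0.699). Cyp26b1, which degrades retinoic acid, was at 21.0 ± 12.9 and 7.65 ± 2.28 CPM (log2 fold change −1.46, SE 0.40), and Mfap1b at 36.7 ± 2.08 and 23.4 ± 4.36 CPM. Without vehicle replicate 2, Fasn (log2 fold change 1.95), Cyp26b1 (−1.80) and Chac1 (−1.37), a glutathione-degrading enzyme of the unfolded protein list, passed over all genes, with edgeR adjusted p of 0.0124, 0.0481 and 0.0481. Without vehicle replicate 3 their log2 fold changes were 1.03, −0.87 and −0.64.

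**Figure D4:**
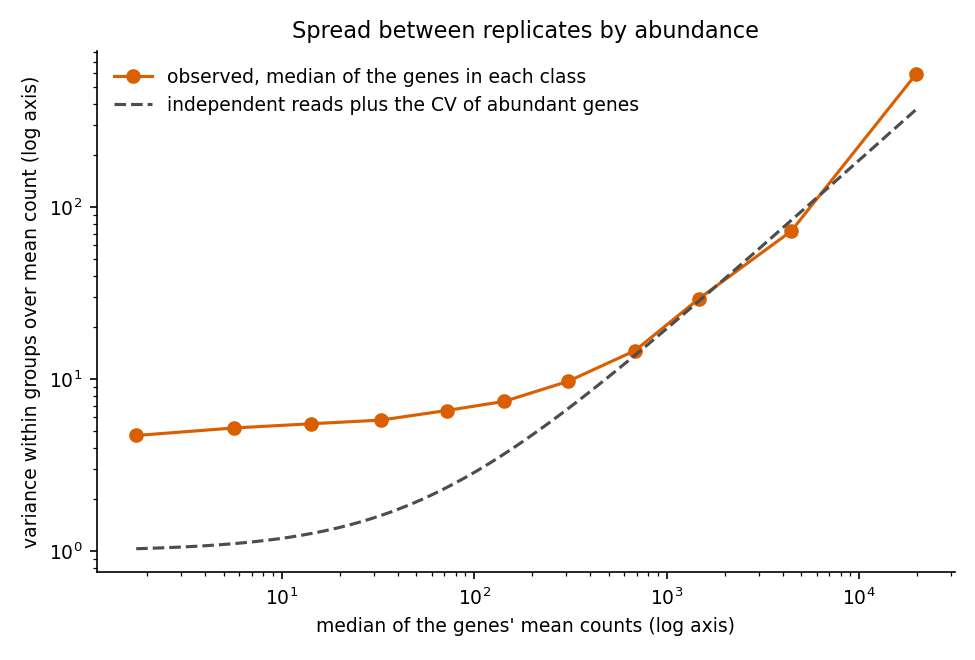
Variance within groups divided by the mean count (y axis, log scale) against the median of the genes' mean counts (x axis, log scale) in 11 classes of abundance. Each orange point is the median over the genes of a class, from all 6 libraries. The dashed line shows independent reads plus the 13.7% coefficient of variation of genes above 1000 counts. The ratio was 5.51 for genes of 10 to 20 counts and 592 for genes above 10000 counts, where it also lay above the dashed line.

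Genes with a mean of 10 to 50 counts had a variance within groups of 5.68 times the mean, where independent reads plus the spread of abundant genes give 1.46. On simulated libraries with the spread of these data, 2-fold changes were recovered in 42.4% of genes and in 94.8% of genes of at least 50 CPM, and 1.5-fold changes in 8.06%. Each simulation changed 200 genes, and the adjusted threshold is stricter where few genes change. These shares can therefore overstate recovery in the real data, where Scd1 at 1.88-fold had an edgeR adjusted p of 0.563.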

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

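The fits without Rn45s and on counts divided by reads per molecule, and every alternative for the Reactome sets, were chosen after the data were seen. No gene passed under another scaling, the stricter filter, the non-robust fit, DESeq2, limma-voom or the added fits. The log2 fold threshold was applied to the genes called in the main fit, of which there were 0, so it could add none. Without a filter 13 genes passed (Fasn, Scd1, Hbb-bs, Hbb-b1, Hba-a1, Sln and Tppp3 higher; Cyp26b1, Slc7a2, Lor, Dsp, Krt15 and Dmkn lower); the median prior degrees of freedom were 18.3 with the filter and infinite without it, which gives smaller p-values to like differences. With 1 library left out, 0 to 3 genes passed, the 3 without vehicle replicate 2. Lists past the threshold numbered 0 with an estimated correlation and 0 with fry, and 11 to 15 in the other fits; Reactome sets numbered 0, 0 and, with 1 library left out, 2 (without farnesol replicate 1) to 32 (without farnesol replicate 3). Apart from the fewer degrees of freedom that camera uses with an estimated correlation, the cause of these differences between fits was not tested.

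In every refit that kept the preset correlation, 6 lists were called: adipocyte markers, complex I, complexes II to IV, ATP synthase, mitochondrial ribosome and import, and fatty acid uptake and oxidation. Neutrophil and mast cell markers were also lost without a filter (0.16) and with the block (0.32), and the stricter filter and the divided counts lost macrophage markers. PPAR targets (0.17) passed without vehicle replicate 3, fast fibre genes (0.15) without vehicle replicate 2, calcium handling without vehicle replicate 1 (0.05) or 2 (0.05), fibroblast markers (0.14) without farnesol replicate 2, and Schwann cell markers without farnesol replicate 3 (0.19) or a filter (0.40). Skin markers, testable only without a filter, also passed there. With other libraries left out the medians of these lists were as low as 0.00 for PPAR targets (without vehicle replicate 1), −0.07 for fast fibre genes and −0.06 for calcium handling (without vehicle replicate 3), and 0.00 for fibroblast markers (without farnesol replicate 1 or 3). Library totals added the inflammation (−0.20) and interferon (−0.13) lists. Of 2796 alternative values for 168 single genes, 11 passed and 23 had another sign; leaving out 1 library moved the log2 fold change of 123 of these genes by over 1.5 times. The excess of detected genes was 57.7 at 1 CPM and 78.7 after thinning to the smallest total.

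The replicate numbers of the titles, from which the numbers in the file names differ, did not pair the libraries: deviations of libraries with the same title number correlated at 0.04, 0.06 and −0.02, and no vehicle and farnesol library correlated above 0.06. With the block of title numbers (replicate block) 0 genes, 12 lists and 22 Reactome sets passed. The fits without mitochondrially encoded transcripts were not run, since none was listed. Depth limits low genes most; if their excess spread came from copied reads alone, about 5.22 reads would stand for 1 independent molecule.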

Other observations

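Except for the Reactome test, the tests in this part were chosen after the patterns they weigh had been seen; after first results were seen, the members counted in the leave-out of adipocyte markers were changed and a margin of 1 SD was added to the test of slow fibres. Genes named in this part other than Scd1 and Fasn were chosen after their values were seen. Among 777 Reactome sets, 22 passed camera at the preset correlation, with 0 of them lower after farnesol and 0 past the threshold with an estimated correlation. Mitochondrial translation (70 of 86 genes higher, median log2 fold change 0.13, adjusted p = 0.000605; adjusted p = 0.978 with an estimated correlation) joined respiratory electron transport (59 of 64 higher, median 0.18, 7.9e-10; 0.978). Peptide chain elongation, which is mainly cytosolic ribosomal proteins, had 72 of 83 genes higher with a median of 0.09 (adjusted p = 0.00639; 0.978 with an estimated correlation). Of the 10 splits of the 6 libraries into 3 and 3, 3 gave at least 22 sets and the highest other split gave 71, from vehicle replicates 1 and 3 with farnesol replicate 1 against the rest, which points to structure among the samples or to genes that vary together within sets, not told apart here; 10 splits are too few for a share under 0.05.

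Markers of some other cell types were too scarce to test. Of 18 T and NK cell markers listed, 0 passed the filter, with 12 to 46 counts per library in all. Of 13 B and plasma cell markers listed 2 passed; Jchain, the joining chain of secreted antibodies, had 163, 0 and 54 counts in farnesol replicates 1, 2 and 3 and 31, 0 and 9 in vehicle replicates 1, 2 and 3. Of 12 skin markers listed 3 passed, and vehicle replicate 1 held 525 counts of the list against 98 to 210 in the other 5 libraries. Lor, Dsp and Krt15 had 68, 65 and 62 counts in vehicle replicate 1 and 0 in each other library, and Dmkn 52 against 0 to 2, so these 4 genes of the fit without a filter rested on vehicle replicate 1. In that fit 7 of the 10 splits, the real one included, gave at least 13 genes, and the highest other gave 46, too few splits for a share under 0.05. Of the 6 sex-linked transcripts 2 were tested: Xist had 1475 to 2146 counts per library, and of the Y-linked genes Ddx3y had 1 count in vehicle replicate 1 and the rest were listed at 0.

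The subunits of oxidative phosphorylation were higher after farnesol (76 of 81, median log2 fold change 0.20). A larger share of slow fibres stays open: slow contractile genes overlapped between groups by less than their spread (lowest farnesol minus highest vehicle library −0.19, SD within groups 0.32). The farnesol mean, 0.25 above the vehicle mean, rested on farnesol replicate 2 (0.55, against −0.11 in replicate 1, the highest for the subunits, and −0.06 in replicate 3). It also rested on a low vehicle replicate 3 (−0.41, against −0.05 and 0.07 in vehicle replicates 1 and 2). A single unusual library may account for much of the shift: without farnesol replicate 1, which was low in Rn45s, the median was 0.10, 47.6% of its value. A trend with transcript length stays open, because the median was 0.11 after its removal, 55.5% of its value, as does a share of non-muscle cells, because 5 isoforms of striated muscle exceeded 3 used elsewhere by 0.0921 (medians 0.31 and 0.22). The real split gave 13 lists past the threshold and the highest other 15, with 3 of 10 splits at 13 or more, too few splits for a share under 0.05; for the subunit median itself the highest other split gave 0.17, and an effect of farnesol stays among the open explanations.

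Adipocyte markers were higher in every farnesol library mean than in any vehicle mean, but 3 of the 10 splits, the real one included, gave as large a median shift (highest other 0.37, real 0.34). Dependence on 1 library for most of the shift is argued against, since the lowest median with 1 library left out was 0.22 (without vehicle replicate 2), 64.3% of the full value of 0.34; counting instead the members tested with all 6 libraries, as first done, it was 0.25, also over 50% of it. More fat tissue in the farnesol samples may account for the shift, because 5 genes restricted to adipocytes and outside lipid synthesis had a median log2 fold change of 0.87, 0.954 times that of Scd1, Fasn and Acly. Among these 5 genes, the abundant Cfd (91.2 ± 33.9 to 114 ± 21.1 CPM, log2 fold change 0.33, SE 0.25) and Adipoq (0.46, SE 0.25) also rose, but by less than this median. Their difference from it was not tested and their standard errors are wide, so they do not decide on more fat tissue. Car3 and Lpl stood at 0.18 each, but muscle also expresses both, so their values do not decide the question either. An effect of farnesol on lipid synthesis in muscle or fat stays open.

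No gene passed over all genes in edgeR with the filter, DESeq2 or limma-voom (0 in each; 13 in edgeR without the filter), and 351 genes, 3.01%, had an unadjusted edgeR p under 0.05 where chance gives 5%. Copied reads may be a reason that no gene passed in the filtered fit. Genes with a mean of 10 to 50 counts varied within groups by 5.68 times their mean. That is 3.89 times what independent reads and the spread of abundant genes give. With 0 genes past the threshold in the real split, 10 of 10 splits give at least as many by construction, so this count decides nothing. The highest other split gave 5. At unadjusted p under 0.05 the other splits gave 342 to 816 genes from the same reads, so copied reads alone do not set the 3.01%. In simulated data 42.4% of 2-fold changes were recovered, and at 50 CPM or more, which 58 of 335 of these genes reached, 94.8% of 2-fold and 25.8% of 1.5-fold changes. These shares hold with 200 genes changed at once and can be lower where few genes change, so they do not exclude 2-fold changes here.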
